A study of Mus musculus with 74 samples.

How the data were processed

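HPC-7 is a mouse haematopoietic progenitor line grown with stem cell factor. RNA-seq was read in 15 libraries of 6 groups, and promoter capture Hi-C in 3 conditions. Per the labels, RNA-seq cells carried an inducible short hairpin RNA against luciferase (Luc, the control), Stag2, Rad21 or Smc1a, and hairpins were induced with doxycycline for 72 h. Progenitor (HPC) libraries were taken then. Erythroid-induced (Ery) libraries were taken after a further 48 h with erythropoietin (EPO) at 4 U/l and less stem cell factor. Stag2, Rad21 and Smc1a encode subunits of cohesin, the ring complex that holds DNA loops. The HPC interaction list came from untransduced cells and the Ery lists from cells with the Luc or the Stag2 hairpin, so the HPC list differs from both others in transduction as well as in stage. Chromatin immunoprecipitation samples were not analysed here.

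The RNA-seq values are raw read counts per transcript identifier, 1 deposited table per library. Reads were aligned with STAR 2.4.0 and counted with HTSeq on mouse build mm10, per the submitters' processing notes. The counting settings, the strandedness and the annotation release are not given in the sources used here, so reads of overlapping or near-identical transcripts cannot be told apart. The last 5 lines of each table name no transcript and were left out. Reads in no annotated feature came to 9.19% to 18% of the counted total per library, and ambiguous reads to 24.2% to 26.9%. Assigned counts ran from 22288469 to 33355332 per library. The most counted identifier took 25.8% to 33.6% of them.

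Of 55943 identifiers, 18065 passed edgeR's filterByExpr. Counts were scaled with TMM and fitted in 1 quasi-likelihood model of all 15 libraries with a mean per group (edgeR 4.0.16, R 4.3.3). Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test with a threshold of 0.05, and each standard error was taken from the fold change and the F statistic. The common biological coefficient of variation was 0.09. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.43 to 58.5, so none were merged. Groups held 3 libraries, except HPC shSmc1a, Ery Luc and Ery shStag2 with 2 each. The labels do not say whether numbered libraries came from separate cultures or hairpins, so p-values measure the spread between these libraries, which may be technical. Titles of the HPC libraries carry the word "inhibitor", which the labels do not explain and which the Ery titles lack. Stage and any batch that goes with it therefore cannot be separated.

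The model was tested on simulated data before use. For shStag2 against Luc in HPC, 18065 transcripts were simulated. Of those changed 1.5-fold 22 of 67 were recovered, of those changed 2-fold 43 of 67 and of those changed 4-fold 54 of 66. There were 6 false calls among 125. For shStag2 against Luc in Ery the numbers were 26 of 67, 33 of 67 and 53 of 66, with 6 false calls among 118. Simulated counts were drawn independently at the fitted trend of the spread, with no further difference between HPC libraries of a group. The real HPC libraries had such a difference, described below, so these rates need not hold for them.

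Neither of the reference tables used here pairs the transcript identifiers with gene symbols. Transcripts are therefore given by identifier, the first 2 that rose and the first 2 that fell by the rule below for shStag2 against Luc in HPC. The planned tests of gene lists on transcript levels, the check of the targeted genes and the join of transcript levels with promoter interactions were not run.

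The promoter capture lists hold pairs of HindIII fragments with a score, which the deposited lists give for interactions scoring 5 or more. Per the labels' protocols, chromatin was digested with HindIII and promoters were captured with hybridisation beads. Each of the 3 lists pools 2 libraries, so a difference between lists has no replicate check and no p-value is given. The software that made the score and the read depth are not given in the sources used here. The score is the authors' and was used only to rank or filter interactions within a list.

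A fragment in the capture column was given the symbols of protein-coding genes of GRCm38.p6 (mm10) whose annotated start or end lies in it. This named 16720 of 21900 genes. The gene table gives no exons, so positions are stated relative to gene starts and ends. An interaction was shared when both fragments were identical in the other list, and exact binomial intervals at 95% cover counting error only. For each gene, interactions on its captured fragments were summed, and a gain or loss meant a difference of at least 2. A gene with 2 captured fragments, such as Spi1, Epor or Mpo, can thus count the same other end for each of them. Neighbouring fragments are not independent, and many genes share a fragment. Some items are not reported here.

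Groups of genes came from 21 lists. The median log2 ratio of interactions (with 1 added) of each list was ranked among 10000 random lists of equal size matched on mean interactions, as a description of these lists. In simulation, a list of 30 genes with 1.5-fold more interactions passed the 95th percentile in 19 of 20 runs and an unchanged list in 0 of 20. The simulated counts had only independent Poisson noise per gene. These rates need not hold for the real lists, where genes share fragments and the spread between pools is unknown.

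The design, the tests, the alternatives planned, the gene lists and the rule for named items were fixed before the data were examined. The rule names the cohesin genes and 14 blood genes (Gata1, Gata2, Klf1, Hbb-bt, Hba-a1, Epor, Alas2, Kit, Cd34, Etv6, Spi1, Mpo, Meis1 and Hoxa9), and the 5 largest gains and losses of interactions per pair of lists. For transcripts it takes the largest changes past the threshold with non-overlapping libraries and a mean of at least 5 CPM in the higher group. Fits within library sets gave each group a mean per set, with Ery libraries kept in the first set and a lone library assumed to vary like the other groups. The use of the gene lists on interaction counts, the choice of list members to name, the values within chromosomes, the regions of contact between chromosomes, the sets of HPC libraries, the search for their difference in Ery and the comparison of knockdowns without a common library were chosen after the data had been seen. Alternatives covered scaling, filtering, the test, the libraries fitted, the replicate number, a minimum fold, the score threshold, the tolerance of the match and equal list lengths. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the interaction lists and figures.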

Results

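The study set cohesin loss in blood progenitors beside erythroid differentiation. The progenitor line HPC-7 was sequenced with hairpins against luciferase, Stag2, Rad21 (3 HPC libraries each) and Smc1a (2 HPC libraries). EPO-induced Ery cells were sequenced with the luciferase or the Stag2 hairpin (2 libraries each). Assigned counts ranged from 22395582 to 31281941 in HPC Luc, 23968631 to 33355332 in HPC shStag2, 22288469 to 33274970 in HPC shRad21 and 22981285 to 26044961 in HPC shSmc1a. Ery Luc libraries held 27229662 and 32324027 and Ery shStag2 libraries 26537468 and 31297629. Promoter capture lists covered untransduced HPC, Ery Luc and Ery shStag2 cells with 112183, 123042 and 130734 interactions, each list being a pool of 2 libraries without a replicate.

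The first comparison asked how promoter contacts differed between progenitors and EPO-induced cells. Genes of heme synthesis and iron handling had more listed interactions after EPO, with 13 of 19 members gaining at least 2 and 3 losing. Alas2, the erythroid enzyme that starts heme synthesis, went from 0 to 4, Abcb10 from 2 to 11, Uros from 6 to 14 and Alad from 103 to 126, while Abcb6 went from 32 to 18 and Ppox from 20 to 10. Mast cell, basophil and eosinophil markers went the other way, with 7 of 14 losing and 4 gaining, among them the mast cell protease gene Cpa3 from 14 to 1 and Hpgds from 7 to 2. Cd34, a surface marker of progenitors, went from 9 to 1. Most contacts of Alas2 and Cd34 scored under 7, and with scores of at least 7 Alas2 went from 0 to 1 and Cd34 from 1 to 0. Alas2 lies on chromosome X, whose share of listed interactions was 1.47% in HPC and 2.81% in Ery Luc.

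The median change of the heme and iron list lay at the 98.2 percentile of matched random lists and that of the mast cell list at the 2.88 percentile. Of 20 lists with members, 2 lay outside the 5th to 95th percentiles by the median, and chance gives 2.0. By the mean 5 did, heme and iron genes at 99.4, mast cell genes at 1.97, S-phase genes at 99.8, immediate-early genes at 1.49 and cohesin genes at 97.2. With interactions within chromosomes alone, the heme and mast cell lists lay at 99.1 and 3.27. The immediate-early list, with 11 of 21 members losing and 5 gaining, then lay at 1.19, and the S-phase list, with 11 of 23 gaining and 2 losing, at 96.9, so that 4 of 20 lists lay outside by the median.

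Erythroid genes as a group were spread, with 14 of 31 gaining and 8 losing, at the 67.8 percentile. The embryonic globin gene Hbb-bh1 went from 0 to 13 interactions. Tal1 went from 45 to 35 and Hemgn from 25 to 15. Gata1, the erythroid master regulator, had 24 interactions in HPC and 13 in Ery Luc, on a captured fragment at X:7974091-7980606 that holds 1 end of the annotated gene. Klf1, another erythroid transcription factor (8:84898227-84903910, gene start), had 15 and 18, and 2 fewer rather than more when scores of at least 10 were counted. Epor, the EPO receptor, had 11 and 18 and Hba-a1, an alpha-globin gene, 1 and 5, but 1 in both with scores of at least 7. Stem and progenitor genes moved both ways, 13 of 26 gaining and 9 losing, with Hlf from 49 to 22, Msi2 from 16 to 5, Runx1 from 4 to 11 and Mycn from 27 to 46. Kit had 6 in both lists, Gata2 11 in both, Meis1 1 and 3, and Etv6 7 and 14. Myeloid genes gained at 9 of 25 and lost at 6, with Csf1r from 12 to 2, Cebpa from 10 to 3 and Prtn3 from 3 to 19.

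Single captured fragments differed by far larger amounts. Interactions went down from 66 to 1 at Hgf (5:16551190-16554537), from 44 to 2 at the platelet selectin gene Selp (1:164100267-164119571), from 99 to 44 at Lsr and Usf2, from 76 to 27 at Slc20a2 and Smim19, and from 88 to 40 at Dse. They went up from 7 to 87 at A430033K04Rik (5:138620014-138625253), from 52 to 112 at the spindle checkpoint gene Mad2l1 (6:66534905-66540307), from 6 to 63 at Sh3kbp1, from 18 to 71 at Mroh2a and from 22 to 72 at Tmem164. The gains at A430033K04Rik and Mad2l1 came from listed interactions with other chromosomes, and within their chromosomes they had 7 and 5, and 9 and 7. Sh3kbp1 and Tmem164 lie on chromosome X, whose share of listed interactions was 1.47% in HPC and 2.81% in Ery Luc.

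Across the genome, the same fragment pair was listed in Ery Luc for 50938 of the HPC interactions, a share of 45.4% (exact interval 45.11 to 45.7). The share was 25.3% for HPC scores of 5 to 6 and 96.5% for scores of 20 or more. Ery Luc contacts reached farther, with a median distance of 214 kb against 154 kb, and 7.05% against 1.15% of contacts within a chromosome spanned over 1 Mb. Contacts between chromosomes made up 7.14% of the Ery Luc list (6.999 to 7.288) and 0.469% of the HPC list (0.4297 to 0.5106). Contacts of a region of chromosome 4 with that chromosome's unplaced scaffold 4_GL456216_random, 142 in Ery Luc and 45 in HPC, were counted among them. Fragments captured on chromosome X held 1.47% of the HPC list, 2.81% of the Ery Luc list and 2.36% of the Ery shStag2 list. Gains at Alas2, Stag2, Smc1a, Sh3kbp1 and Tmem164, all on X, cannot be told from this wider difference. Gata1, also on X, had fewer interactions in Ery Luc. At least 2 interactions were gained at 6144 of 15756 genes and lost at 3846. As the depth of the libraries is unknown and the HPC cells were not transduced, these differences compare lists, not conditions. With scores of at least 7 the balance turned, 47.3% of 5487 changed genes then having gained.

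**Figure D1:**
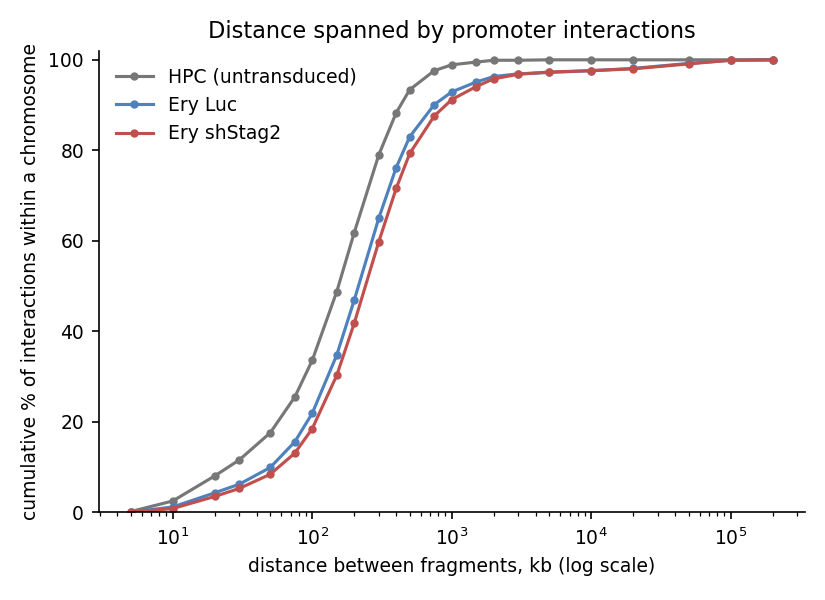
Cumulative percent of interactions within a chromosome (y axis) by the distance between the fragments in kb (x axis, log scale) for the 3 deposited lists, 1 line each. At 200 kb the lines stand at 61.8% for HPC, 46.9% for Ery Luc and 41.8% for Ery shStag2.

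The next comparison asked what Stag2 knockdown did to promoter contacts after EPO. Spi1, which encodes the myeloid and lymphoid transcription factor PU.1, had 29 interactions in Ery Luc and 6 in Ery shStag2, with 2 in common. They lie on fragments at 2:91080805-91084236, over the gene start, and 2:91108722-91123643, over its end. Both fragments had fewer contacts in Ery shStag2. Most of the Ery Luc contacts, most of the fall and both contacts named next were on the fragment over the gene end. Most contacts listed in Ery shStag2 were on the fragment over the gene start. Mybpc3 also has an annotated start or end on these fragments, so the counts cannot be given to Spi1 alone. The contact of the fragment over the gene end with 2:91233987-91239729 in Ddb2, 121 kb away, scored 10.57 in Ery Luc. It was not listed in Ery shStag2. The contact of the same captured fragment with 2:91198969-91207879 over Acp2 and Nr1h3 scored 10.03 in Ery Luc and 6.79 in Ery shStag2. Klf1 went from 18 to 6, with 3 in common. Gata2 went from 11 to 5 and Gata1 from 13 to 8.

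Mpo, the myeloperoxidase gene of granulocyte precursors, went the opposite way, from 11 to 28, and Kit, the stem cell factor receptor, from 6 to 13. The Mpo counts sum 2 captured fragments. In Ery shStag2 its highest-scoring contacts, at 12.18 and 8.75, had the same other end. Meis1 had 3 and 6 interactions, Etv6 14 and 16, Epor 18 and 17, Alas2 4 and 2, Hba-a1 5 and 1 and Cd34 1 and 0. The cohesin genes Stag2, Smc1a and Stag1 had 6, 6 and 1 interactions in Ery Luc and 0, 1 and 0 in Ery shStag2, none scoring over 7.59. In HPC they had 0, 3 and 1, and Smc1a had 1 fewer in Ery Luc than in HPC with scores of at least 7. Rad21, Smc3, Hbb-bt and Hoxa9 had no annotated start or end on a listed captured fragment. With scores of at least 7, Gata1 had 2 more interactions in Ery shStag2 and Epor 1 more, against the directions above. The changes at Spi1, Klf1, Mpo and Kit shrank to -8, -5, +4 and +1.

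**Figure D2:**
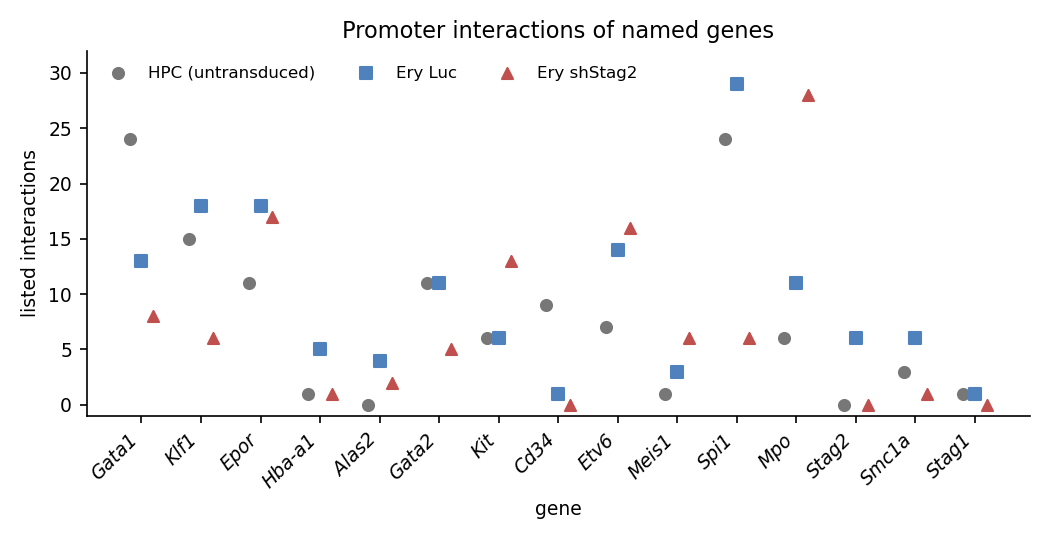
Listed promoter interactions (y axis, count) of 15 genes (x axis) in the HPC, Ery Luc and Ery shStag2 lists, 1 point per list and no replicates. Spi1 had 24, 29 and 6 interactions and Mpo 6, 11 and 28, each summed over 2 captured fragments.

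By group, cohesin genes lost interactions at 7 of 16 members and gained at 3, a median at the 3.15 percentile of random lists, among them Stag3 from 24 to 9 and Pds5a from 15 to 10, with Pds5b from 3 to 9. Most Stag3 contacts in Ery Luc were between chromosomes, and within its chromosome it had 1 and 7. From HPC to Ery Luc the cohesin list had gone the other way, with 9 of 16 members gaining and 4 losing, and its mean contacts per gene were 5, 7.44 and 5.62 in HPC, Ery Luc and Ery shStag2. Stag3 weighs on these means, as it went from 1 in HPC to 24 in Ery Luc but stayed at 1 within its chromosome. Stag2 and Smc1a lie on chromosome X, whose share of listed interactions was 1.47%, 2.81% and 2.36% in HPC, Ery Luc and Ery shStag2. Within chromosomes the change of the list from HPC to Ery Luc lay at 87.4 by the median and 86.9 by the mean. Mast cell, basophil and eosinophil genes gained at 10 of 18 and lost at 4, at the 96.6 percentile, with Cpa3 from 1 to 10. These were the 2 of 20 lists outside the 5th to 95th percentiles by the median, where chance gives 2.0. By the mean 5 did, these at 0.22 and 98.1, heme and iron genes at 3.99, cytokine targets at 2.68 and genes of the G2 and M phases at 95.8. Within chromosomes the cohesin list, with 5 of 16 members losing and 4 gaining with shStag2, lay at 6.64 by the median and 4.28 by the mean. The mast cell list lay at 98.3 by the median but at 87.8, inside the range, by the mean. Both the EPO and the Stag2 comparison use the Ery Luc list, so a list high in one by chance tends to be low in the other.

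Within chromosomes, 5 of 20 lists lay outside by the median, the mast cell list and 4 others. Erythroid genes lay at the 4.04 percentile and heme and iron genes at 4.01. Of 31 erythroid genes, 12 lost and 7 gained, with Ank1 from 7 to 0, but Car2 from 67 to 90 and Tal1 from 35 to 47. Of 18 heme and iron genes, 10 lost and 3 gained, among them Uros from 14 to 1 and Urod from 16 to 7, with Fech from 9 to 18. Myeloid genes then lay at 99, with 11 of 24 gaining and 8 losing, and immediate-early genes at 97.9, with 11 of 21 gaining and 4 losing. By the mean the myeloid list lay inside the range, at 90.5. The erythroid, heme and iron, and immediate-early lists lay at 1.08, 0.29 and 97.2 by the mean. With contacts between chromosomes included, these 4 lists lay inside the 5th to 95th percentiles by the median, at 35.4 for erythroid, 24.2 for heme and iron, 94.2 for myeloid and 89.6 for immediate-early genes. Targets of cytokine signalling lay at 5.75, with Bcl2l1 from 31 to 19 and Pim2 from 27 to 15.

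The largest gains of single captured fragments were at Cmip, from 40 to 88, Dse, from 40 to 79, Lsr and Usf2, from 44 to 82, Zfp184, from 29 to 66, and Plagl2 and Pofut1, from 7 to 41. The fragments of Cmip, Dse, and Lsr with Usf2 had 80, 88 and 99 in HPC. The largest losses were at A430033K04Rik, from 87 to 9, Sh3kbp1, from 63 to 16, Zfp157, from 46 to 5, Tmem164, from 72 to 34, and a fragment with Fbxo46, Qpctl and Snrpd2, from 60 to 28. Within chromosomes A430033K04Rik had 5 and 8 and Zfp157 had 9 and 4.

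Of the Ery Luc interactions, 55007 were listed in Ery shStag2, a share of 44.7% (exact interval 44.43 to 44.98). The share was 26% for scores of 5 to 6 and 91.3% for scores of 20 or more. Median distances were 214 kb and 241 kb, and 8.81% of Ery shStag2 contacts within a chromosome spanned over 1 Mb. At least 2 interactions were gained at 5274 of 16475 genes and lost at 4206. Of the Ery Luc interactions, 41.4% were listed in HPC. With scores of at least 10 the shares of Ery Luc contacts found in Ery shStag2 and in HPC were 50.7% and 45.4%. Without replicate lists it cannot be said how much of either share reflects the cells.

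A region of chromosome 1 with Cxcr4, the receptor of the homing chemokine Cxcl12, and Mcm6 had 365 interactions with a region of chromosome 5 with Stag3, Mcm7 and A430033K04Rik in the Ery Luc list, and 0 in either other list. Fragment midpoints ran from 127775460 to 128898660 on chromosome 1 and from 137779538 to 139152133 on chromosome 5. The interactions came from 30 captured fragments, with a median score of 9.24. They include contacts of A430033K04Rik, Zfp157 and Mcm6, the last of which went from 3 in HPC to 40 in Ery Luc in all and from 3 to 18 within its chromosome. Regions of chromosomes 16 (with Dscam and Pcp4) and 19 (with Got1 and Hpse2) shared 130 interactions in Ery Luc alone, and regions of chromosomes 17 (with Haao and Mta3) and 3 (with Tet2) shared 41 in Ery shStag2 alone. A region of chromosome 6 with Mad2l1 met a region of chromosome 11 near Havcr1 and Timd4 in all 3 lists. They shared 50, 109 and 108 interactions in HPC, Ery Luc and Ery shStag2, of which the Mad2l1 fragment carried 86%, 95.4% and 95.4%.

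**Figure D3:**
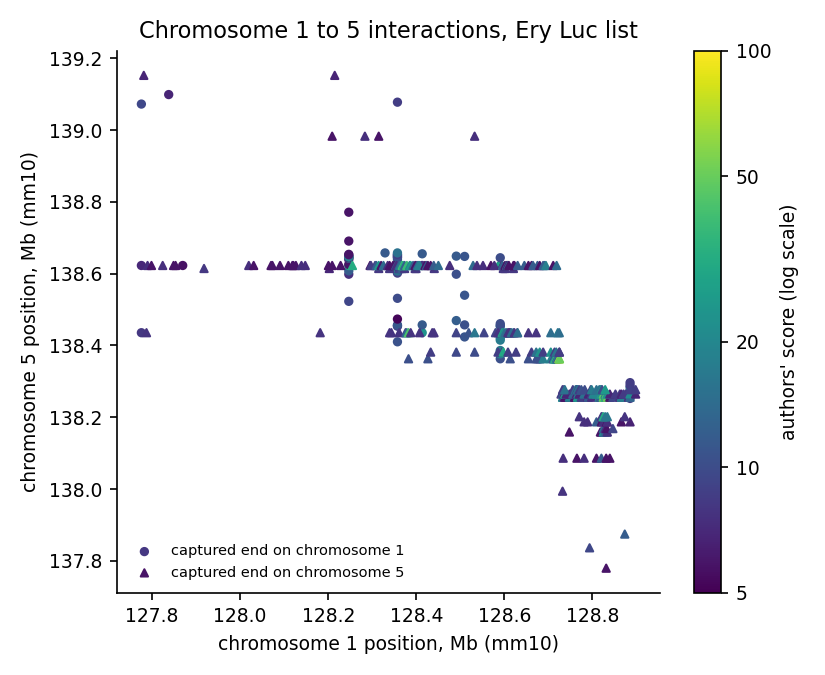
Interactions between chromosomes 1 (x axis, Mb) and 5 (y axis, Mb) in the Ery Luc list, mm10, 1 marker per interaction at the fragment midpoints, coloured by the authors' score on a log scale. The 365 markers fill 2 opposite corners, 238 and 127, that meet between 128725576 and 128729194 on chromosome 1 and between 138296356 and 138362787 on chromosome 5.

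The RNA-seq comparisons asked which transcripts followed cohesin loss in progenitors. Transcript ENSMUST00000023934.6 averaged 6.21 ± 0.91 CPM in HPC Luc (SD, n = 3) and 0.201 ± 0.19 in HPC shStag2 (n = 3), 0.167 ± 0.1 in shRad21 (n = 3) and 0.0786 ± 0.05 in shSmc1a (n = 2). ENSMUST00000026911.4 fell from 13.9 ± 1.4 CPM to 1.68 ± 0.19, 1.32 ± 0.38 and 1.25 ± 0.063 in the same order. ENSMUST00000100070.2 rose in all 3 knockdowns, from 2.3 ± 0.11 to 11.2 ± 5.7, 8.5 ± 1.6 and 6.97 ± 0.42 CPM. ENSMUST00000008016.2 rose with shStag2 and shRad21, from 1.87 ± 0.27 to 6.03 ± 2.5 and 7.27 ± 1.9 CPM, and stood at 2.85 ± 2.3 with shSmc1a.

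For shStag2, edgeR's quasi-likelihood test gave log2 fold changes of -4.74 (SE 0.27, adjusted p = 6.55e-09) and -3.04 (SE 0.16, adjusted p = 5.2e-09) for ENSMUST00000023934.6 and ENSMUST00000026911.4. ENSMUST00000100070.2 and ENSMUST00000008016.2 changed by 2.26 (SE 0.27, adjusted p = 5.44e-05) and 1.64 (SE 0.34, adjusted p = 0.00899). The first has shStag2 libraries near or at 0 counts (0.228, 0.375 and 0 CPM), so the size of its fold change depends on the prior count.

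In total, 571 of 18065 transcripts changed with shStag2, 309 higher and 262 lower, and 150 of them by at least 2-fold, 61 higher and 89 lower. Principal components set the HPC libraries numbered 3 and both shSmc1a libraries apart from the other HPC libraries, a difference the labels do not name. Within the first of these sets 1182 transcripts changed, while the second holds only 1 library each of Luc, shStag2 and shRad21. Without Luc replicate 1, shStag2 replicate 1 or shStag2 replicate 2, 367, 341 and 357 transcripts passed.

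The shRad21 cells changed at 1419 transcripts, 706 higher and 713 lower, and 287 by at least 2-fold, 134 higher and 153 lower. Within the first set of libraries 2278 changed. Without Luc replicate 1 or shRad21 replicate 2, 868 and 861 passed. With only the 6 libraries compared, 631 passed.

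The shSmc1a cells changed at 782 transcripts, 425 higher and 357 lower, and 192 by at least 2-fold, 114 higher and 78 lower. Their libraries belong to the second set, where Luc replicate 3 is the only control, so most of this comparison crosses the sets. With the library set as a term 965 transcripts passed, 637 of the 782 among them. Without Luc replicate 1 or 2, 407 and 487 passed, and without shSmc1a replicate 1 or 2, 229 and 303.

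The same transcripts changed in several knockdowns. Of the 571 shStag2 transcripts, 466 (81.6%) also changed with shRad21, 253 rising and 212 falling in both and 1 going opposite ways, where independent lists would share 12.1 and 10.3. The shSmc1a cells shared 251 with shStag2 (137 rising, 112 falling and 2 opposite, against 7.27 and 5.18 for independent lists). They shared 392 with shRad21 (204 rising, 183 falling and 5 opposite, against 16.6 and 14.1). All 3 knockdowns shared 231 transcripts, 125 rising and 106 falling. The covariance of log2 fold changes across transcripts was 0.137 for shStag2 and shRad21, 0.105 for shStag2 and shSmc1a and 0.127 for shRad21 and shSmc1a, with Pearson correlations of 0.714, 0.523 and 0.554. Unchanged groups were also simulated against simulated Luc libraries common to all of them, without a difference between library sets. They gave mean covariances of 0.0436, 0.0437 and 0.0435 and mean correlations of 0.524, 0.454 and 0.449. Shared controls alone can thus give part of such values, though how large a part in these data is not known.

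The knockdowns were therefore also compared without a common library, 1 against Luc replicates 1 and 2 in the first set and the other against Luc replicate 3 in the second. Of 1182 transcripts changed by shStag2 in the first set, 83.5% moved the same way with shRad21 and 78.8% with shSmc1a in the second, against 57.5% and 54.9% of the other transcripts. Of 2278 changed by shRad21 in the first set, 76.5% moved the same way with shStag2 and 76.8% with shSmc1a in the second, against 54.6% and 54.9%.

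Compared directly, shRad21 and shStag2 cells differed at 40 transcripts, 13 higher and 27 lower in shRad21. The count was 459 within the first library set. It was 11, 21, 16 and 89 without shStag2 replicate 1, shStag2 replicate 2, shRad21 replicate 2 and shRad21 replicate 3. DESeq2 gave 113, and a fit of only the 6 libraries 8. The shSmc1a cells differed from shStag2 cells at 376 transcripts and from shRad21 cells at 497. These counts carry the set difference, since both shSmc1a libraries belong to the second set and 2 of 3 libraries of the other groups to the first. With the library set as a term 510 and 675 passed, 291 of the 376 and 382 of the 497 among them. The count against shStag2 was 125, 170, 668, 71 and 141 without shStag2 replicates 1, 2 and 3 and shSmc1a replicates 1 and 2. That against shRad21 was 245, 133, 1578, 65 and 161 without shRad21 replicates 1, 2 and 3 and shSmc1a replicates 1 and 2, and 69 in a fit of only the 5 libraries compared.

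**Figure D4:**
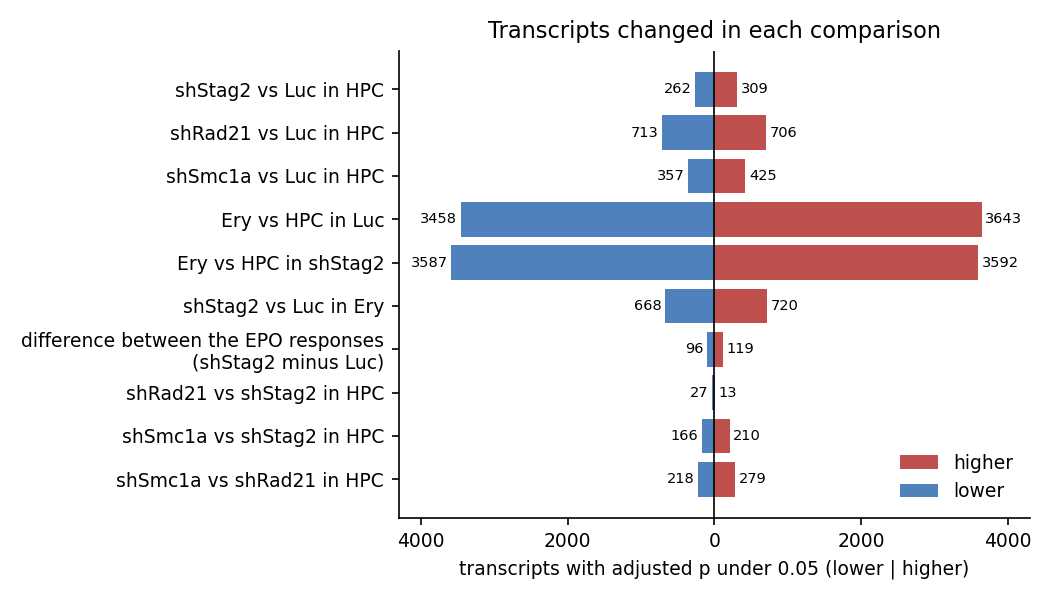
Transcripts with an adjusted p under 0.05 in each comparison (x axis, count, lower to the left and higher to the right of 0), from 1 edgeR fit of 15 libraries. EPO induction changed 7101 transcripts in Luc cells and 7179 in shStag2 cells, the knockdowns 571 to 1419.

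EPO induction in Luc cells raised ENSMUST00000023934.6 from 6.21 to 1550 ± 33 CPM (n = 2), a log2 fold change of 7.95 (SE 0.15, adjusted p = 6.52e-17 by edgeR). ENSMUST00000100070.2 and ENSMUST00000008016.2 rose to 4.83 ± 0.016 and 10.1 ± 0.27 CPM. ENSMUST00000026911.4 did not pass, at 10.8 ± 0.34 CPM (log2 change -0.36, adjusted p = 0.0678 by edgeR). In all, 7101 transcripts (39.3%) changed, 3643 higher and 3458 lower. Of the 2516 that changed at least 2-fold, 675 were higher and 1841 lower. Ery libraries had fewer reads outside annotated features, 9.45% ± 0.073 in Ery Luc (n = 2) against 15.9% ± 0.73 in HPC Luc (n = 3). EPO induction in shStag2 cells changed 7179 transcripts, 3592 higher and 3587 lower, and of 2673 that changed at least 2-fold 622 were higher and 2051 lower. The count was 4595 without Ery shStag2 replicate 2. There ENSMUST00000026911.4 rose by 1.65 on the log2 scale (SE 0.19, adjusted p = 2.86e-06 by edgeR).

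The EPO responses of Luc and shStag2 cells, which share no library, moved most shared transcripts the same way. Of 4976 transcripts that changed in both, 4937 moved the same way, 2613 rising and 2324 falling, and 39 moved opposite ways. A slope was fitted by total least squares, which depends on the scatter of both responses and is not a regression of 1 on the other. Across all tested transcripts it was 0.997 for shStag2 against Luc, with a Spearman correlation of 0.743. Transcripts are not independent replicates. Leaving out Ery Luc replicate 1 or 2 gave slopes of 0.768 and 0.788, and leaving out Ery shStag2 replicate 1 or 2 gave 1.25 and 1.33. Among 6339 transcripts averaging at least 10 CPM the slope stayed between 0.9475 and 1.049 under every such omission.

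A difference between the EPO responses was tested for each transcript, and 215 passed, 119 with a higher and 96 with a lower change in shStag2 cells. ENSMUST00000026911.4 responded differently by 2.01 (SE 0.24, adjusted p = 0.000152 by edgeR) and ENSMUST00000023934.6, near 0 counts in HPC shStag2, by 1.94 (SE 0.37, adjusted p = 0.0105 by edgeR). The responses were weaker in shStag2 cells for 105 of the 215 (68 rising and 37 falling transcripts), stronger for 62 (50 rising, 12 falling), and 48 did not pass the test of the average response. Counts fell to 121 and 123 without HPC shStag2 replicates 1 and 2, to 72 and 69 without Ery Luc replicates 1 and 2, and to 70 and 64 without Ery shStag2 replicates 1 and 2. DESeq2 gave 355.

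**Figure D5:**
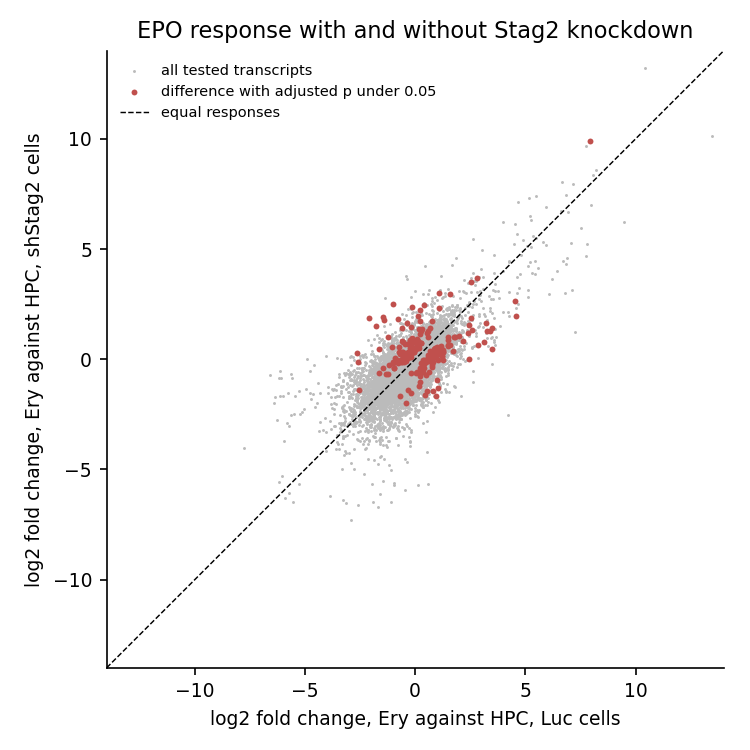
Log2 fold change of Ery against HPC in Luc cells (x axis) and in shStag2 cells (y axis), 1 point per tested transcript (18065), with the 215 transcripts that differ in red and a dashed line of equal response. The total least squares slope of the points is 0.997.

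After EPO, Stag2 knockdown changed 1388 transcripts, 720 higher and 668 lower, and 424 by at least 2-fold, 188 higher and 236 lower. ENSMUST00000023934.6 stood at 1550 ± 33 CPM in Ery Luc and 222 ± 0.25 in Ery shStag2 (n = 2 each), a log2 change of -2.8 (SE 0.14, adjusted p = 1.17e-09 by edgeR). ENSMUST00000008016.2 rose from 10.1 ± 0.27 to 65.8 ± 0.87 CPM and ENSMUST00000100070.2 from 4.83 ± 0.016 to 18.5 ± 0.98 CPM. ENSMUST00000026911.4 fell from 10.8 ± 0.34 to 5.28 ± 1 CPM. Of the 571 transcripts changed by shStag2 in HPC, 296 changed in Ery as well, 181 rising and 109 falling in both, where independent lists would share 12.3 and 9.69. Without Ery Luc replicate 1 or 2, 660 and 678 transcripts passed, and without Ery shStag2 replicate 1 or 2, 676 and 675. With only the 4 Ery libraries fitted, 3701 passed.

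The labels do not say to which library set the Ery libraries belong. On the third principal component (PC3), Ery Luc lay at -8.89 and -7, on the side of the second set of HPC libraries, and Ery shStag2 at 9.95 and 9.46, on the side of the first. The set difference was therefore estimated from shStag2 and shRad21 HPC libraries, at 2750 transcripts, and looked for in other libraries. Of these transcripts, 82.3% moved the same way between Luc replicate 3 and Luc replicates 1 and 2, and 51.7% between Ery shStag2 and Ery Luc. Pearson correlations were 0.484 and 0.0743. Between shSmc1a and Luc replicates 1 and 2 in HPC, 85.2% moved the same way, with a correlation of 0.618. Any other difference between the Ery Luc and Ery shStag2 libraries cannot be told from the knockdown, nor from the difference in EPO response.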

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

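The tests of the between-chromosome contacts, the mean count per gene and the splits of the libraries were chosen after their results had been seen.

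The shStag2 effect differed between HPC and Ery cells for 215 transcripts, by an edgeR test of the difference itself. The named transcripts among them are ENSMUST00000026911.4 with a difference of 2.01 and ENSMUST00000023934.6 with 1.94 on the log2 scale. Both fell with shStag2 in either stage, and the fall on the log2 scale was larger in HPC. In CPM, ENSMUST00000023934.6 fell from 6.21 to 0.201 in HPC and from 1550 to 222 in Ery. Its HPC shStag2 libraries are near or at 0 counts, so the size of its difference depends on the prior count.

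The 365 contacts between chromosomes 1 and 5 stood in the Ery Luc list alone. Shared sequence is argued against, since the same reference served all 3 lists, both others hold 0, and the most frequent captured fragment carries 22.5% of them, while for the Mad2l1 contacts with chromosome 11 that share is 95.4%. Scattered pairs close to the score threshold are argued against by a median score of 9.24, where contacts between chromosomes in the list as a whole had 5.9. All 365 lie in 2 opposite quadrants around 1 point, against at most 253 in 1000 shuffles of the pairing, and a candidate explanation is an exchange between the chromosomes carried by part or all of the Luc cells, which was not checked by sequence. For the 130 contacts between chromosomes 16 and 19, the shares and scores argue the same way (23.8% on the most frequent fragment, a median score of 7.41), but 93 in opposite quadrants against a highest shuffle of 101 leave a rearrangement and a contact of intact chromosomes open.

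Spi1, whose fragments also hold a start or end of Mybpc3, and Klf1 had fewer contacts in Ery shStag2 than in Ery Luc. Most of the fall at Spi1 was on the captured fragment over the gene end. Fewer listed contacts averaged over all genes are argued against, since the mean per gene was 7.91 in Ery shStag2 and 7.54 in Ery Luc. Genes with a similar Ery Luc count did have fewer, with a median change of -2 for those matched to Spi1 and -1 for Klf1. Among them, the change at Spi1 lay at the 0.826 percentile of 605 genes and that at Klf1 at the 2.65 percentile of 1206. Matched in the same way, Gata2 lay at 8.67 and Gata1 at 17.4. Ordinary variation between lists cannot be told apart from an effect of the knockdown, as each list is a single pool and the spread between pools is unknown. An effect of Stag2 loss therefore stays open and untested.

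The 6 libraries of each HPC comparison with 3 per group make 10 splits, too few for a share under 0.05. The real split was the 1 with as many transcripts in each case. It gave 571 for shStag2 against a highest other of 20, 1419 for shRad21 against 0, and 40 for shRad21 against shStag2 with a highest other of 14. The other splits put libraries of both kinds in each group, so any difference between the kinds widens their spread and few transcripts can pass. Their low counts were thus largely set in advance.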

How the results depend on the processing

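The library-set settings, the fits without the most counted transcript, contacts within chromosomes and the score filter on gained or lost genes were chosen after the data had been seen. The cause of a change below was not tested except where fewer samples entered. DESeq2's size factors, the filter of CPM above 1 in at least 2 libraries of a group, and omission of the most counted transcript kept every count of changed transcripts within 1.5 times. All 64 alternatives for the 4 named transcripts in shStag2 against Luc in HPC kept direction and threshold side, and alternatives for their other comparisons were not run. List tests on transcript levels, with the estimated correlation, fry and the block in them, were not run because identifiers were not matched to genes. The read depth behind the contact lists is unknown, which limits what an unlisted contact means.

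Without the filter on low counts, 935 transcripts changed with shStag2 and 1297 with shSmc1a in HPC, 544 differed in EPO response, and shRad21 against shStag2, shSmc1a against shStag2 and shSmc1a against shRad21 gave 232, 943 and 1204. With at least a 2-fold change, shStag2, shRad21 and shSmc1a gave 150, 287 and 192, EPO in Luc and in shStag2 cells 2516 and 2673, shStag2 in Ery 424, the difference in EPO response 71, and the same 3 direct comparisons 9, 89 and 95. DESeq2's Wald test gave 355 for the difference in EPO response, 113 for shRad21 against shStag2 and 756 for shSmc1a against shRad21. Fits of only the groups compared gave 631 for shRad21, 3701 for shStag2 in Ery, 8 for shRad21 against shStag2 and 69 for shSmc1a against shRad21.

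With the library set as a term, counts were 1305 for shStag2, 2727 for shRad21, 2432 for shStag2 in Ery, 810 for the difference in EPO response and 463 for shRad21 against shStag2. Refits of the first set alone gave 1351, 2489, 3069, 1189 and 681 in the same order. Both settings kept the Ery libraries, whose set is unknown, with the first set. The second set gave 161 for shRad21 against shStag2 and 697 for shSmc1a against shStag2. It holds 1 library each of Luc, shStag2 and shRad21, assumed to vary like the libraries of the other groups, so these counts carry little weight. The 231 transcripts shared by all 3 knockdowns became 53 with at least a 2-fold change, 401 with the library set as a term and 0 in simulated unchanged groups, where almost no transcript passed, so that this 0 says nothing of shared controls. With the library set as a term shSmc1a counts stayed within 1.5 times, at 965 against Luc, 510 against shStag2 and 675 against shRad21, but kept only 637 of 782, 291 of 376 and 382 of 497 transcripts.

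With the replicate number as a replicate block, counts were 1270 for shStag2, 2645 for shRad21, 2602 for shSmc1a, 2360 for shStag2 in Ery, 773 for the difference in EPO response and 435, 2105 and 2892 for the 3 direct comparisons. Both shSmc1a libraries belong to the second library set but are numbered 1 and 2. The block thus left the set difference in every comparison with shSmc1a. EPO in Luc and shStag2 cells stayed within 1.5 times at 8281 and 8423. Deviations of same-numbered HPC libraries correlated between 0.0231 and 0.323, 5 of 9 libraries correlated best with their own number, and the Ery pair gave -0.00318, so the numbers are not taken to pair the libraries.

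Leaving out 1 library at a time gave 341 to 548 for shStag2, 861 to 1618 for shRad21, 229 to 1035 for shSmc1a, 4775 to 6935 for EPO in Luc cells, 4595 to 7193 for EPO in shStag2 cells, 660 to 678 for shStag2 in Ery and 64 to 276 for the difference in EPO response. It gave 11 to 89 for shRad21 against shStag2, 71 to 668 for shSmc1a against shStag2, 65 to 1578 for shSmc1a against shRad21, and slopes of 0.768 to 1.33. Fewer samples entered these fits, and an arm with 1 library left was assumed to vary like the others.

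The share of HPC contacts found in Ery Luc, 45.4%, was 43% with scores of at least 7, 40.9% with scores of at least 10, 72% with the other end within 10 kb and 43.1% with equal numbers of top-scoring contacts. For Ery Luc contacts in Ery shStag2, 44.7%, the values were 49.1%, 50.7%, 68.1% and 43.4%, and 47.6% within chromosomes. Genes with gained or lost contacts numbered 5380 with EPO at a change of at least 4 and 5487 with scores of at least 7. With shStag2 they numbered 14309 at a change of at least 1, 4536 at 4 and 4856 with scores of at least 7. Of 120 alternatives for named genes, 85 gave a like value, 29 moved and 6 turned direction. The change from HPC to Ery Luc was -1 for Smc1a with scores of at least 7 and with scores of at least 10, against +3 in the full lists, and -2 for Klf1 with scores of at least 10. The change from Ery Luc to Ery shStag2 was +2 for Gata1 with scores of at least 7, and +1 for Epor at either threshold.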

Other observations

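The ranks of gene lists by contacts and the tests of opposite directions were chosen after the data had been seen, except the one with the Luc response, which was set down before its result.

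Other groups of genes lay inside the 5th to 95th percentiles by the median of their promoter contacts. Ribosomal protein genes gained at 38 of 79 and lost at 17 between HPC and Ery Luc (86.6 percentile), and gained at 24 and lost at 27 of 78 between Ery Luc and Ery shStag2 (28.4 percentile). Interferon-response genes gained at 7 and lost at 10 of 30 (21.9 percentile), then gained at 10 and lost at 7 of 32 (35.2 percentile). Genes of the G2 and M phases gained at 7 and lost at 6 of 21 with EPO, and at 11 and 3 of 23 with Stag2 knockdown (92 percentile, but 95.8 by the mean and so outside). Hoxa genes gained at 5 of 8 in Ery shStag2, with Hoxa6 at 42, 21 and 31 contacts in HPC, Ery Luc and Ery shStag2. In all 3 lists 36463 of 246363 fragment pairs were present.

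A hypothesis is that Rad21 loss moved progenitors away from the EPO-induced state, though not Rad21 loss alone, as shStag2 gave 231 of 334 (69.2%) opposite to the shStag2 response, whose shared libraries push the pair opposite ways, and 204 of 335 (60.9%) to the Luc response. Of 824 transcripts that changed both with shRad21 and with EPO in shStag2 cells, a pair of comparisons without a common library, 641 (77.8%) went opposite ways. The shStag2 baseline might produce this, but with the EPO response from Luc cells, whose common Luc baseline pushes both comparisons the same way, 549 of 806 (68.1%) still went opposite ways, which argues against the baseline as the whole cause. For shSmc1a the shares were 52.3% and 43%, a difference that was not tested, and with the library set as a term the shRad21 and shSmc1a shares were 74.2% and 61.8% against the shStag2 response, and a batch that goes with stage remains open.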
